A study of Homo sapiens with 6 samples.

How the data were processed

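Gene expression was measured in HEK293T cells, a human embryonic kidney line, after transient transfection with an empty FLAG vector, FLAG-tagged GEMC1 (gene symbol GMNC) or FLAG-tagged MCIDAS. Per the labels' protocols, RNA was taken 48 h after transfection, 25 ng of it was amplified over 16 cycles by whole transcriptome amplification, and 8 µg of cDNA was labelled and hybridized to Affymetrix PrimeView arrays, 1 array per sample. There were 6 arrays, 2 per group. Replicate numbers follow the order of the records and pair no arrays across groups. The labels do not say whether the 2 arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

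The deposited values are log2 expression values per probe set, made by the authors with RMA per the submitters' processing notes, with no version given. Which arrays were normalized together is not given in the sources used here. Array medians lay between 8.41 and 8.51 and the standard deviation over probe sets between 2.07 and 2.18 on the log2 scale. That standard deviation was lowest on the MCIDAS arrays, at 2.07 and 2.10, against 2.14 to 2.18 on the others. The number of arrays limits the precision. The 23 background probe sets averaged 6.32 in controls, 6.23 with GEMC1 and 6.22 with MCIDAS, but ran from 4.42 to 10.9 in controls with their GC content. The GC content of gene probes was not used here, so that mean is a rough mark, under which 14.5% of genes lay in controls. Of the named genes, GMNC, DEUP1 and DNAAF6 lay under it in every group.

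The table held 49395 probe sets, of which 102 array control probe sets were left out of the tests. Of the others, 44988 had 1 gene symbol in the platform annotation, 1832 had several and 2473 had none in the table used, and probe sets of the latter kinds named no gene. Symbols were matched through Entrez identifiers for 44967 probe sets. Each of the 18132 genes was represented by its probe set with the highest mean over the 6 arrays. For 11734 genes there was more than 1 probe set, and where those of a named gene disagreed in sign in the comparison given, their range is stated. Where they agreed in sign the range is given for some genes only, and the value used can be the largest.

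The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided), without a filter on dim genes, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All adjusted p-values for genes are from limma. The fit had 3 residual degrees of freedom per gene and a prior of 2.84 degrees of freedom. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333. Standard errors (SE) of log2 fold changes come from the same fit, and SD is that of the 2 arrays of a group.

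Before the data were examined, 21 gene lists with 763 entries were fixed. They cover multiciliogenesis regulators, centriole amplification, the motile cilium axoneme, dynein arm assembly factors, intraflagellar transport and the BBSome, the Notch pathway, DNA replication and G1/S, mitosis and G2/M, SWI/SNF subunits, p53 targets, the integrated stress and unfolded protein response, the heat shock response, the interferon response, immediate early genes, neuronal genes, airway basal and secretory cell markers, kidney epithelium markers, fibroblast and mesenchymal markers, testis and sperm flagellum genes, ribosomal proteins and the mitochondrial respiratory chain. Of the entries, 705 were measured under the listed symbol, 15 under another symbol of the gene, and 43 were not analysed here. Lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. List medians were also placed among those of 10000 random lists matched on mean value. Random lists are drawn gene by gene and lack the correlation within a real list, and genes are not replicates. These percentiles are therefore descriptive and extreme ones are no test.

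The named genes follow a rule fixed at the same time. It takes GMNC, MCIDAS and GMNN; 9 regulators of multiciliated cells; per comparison the 8 genes with the largest positive and the 8 with the largest negative change among called genes whose arrays do not overlap; and up to 4 called members per list, or the member with the largest change where none was called. Genes named outside the rule are said to be so where they appear.

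The gene test was tested on simulated arrays with 200 changed genes among 18132, over 10 repeats per comparison. For GEMC1 over control it recovered 32.8% of genes changed by 0.5, 93.5% of those changed by 1 and 99.4% of those changed by 2 on the log2 scale, and 7.9% of its calls were false. For MCIDAS over control the shares were 31.7%, 93.9% and 99.6%, with 7.23% of calls false. For MCIDAS over GEMC1 they were 30.1%, 94% and 99.6%, with 6.83% of calls false. The false share was above the nominal 0.05 each time. In 20 simulated runs for GEMC1 over control, camera called a list of 30 genes shifted by 0.3 in 20 runs and called 0 of 400 unshifted lists.

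The alternatives fixed beforehand were the median or mean of a gene's probe sets, probe sets tested one by one, filters on dim genes, renewed quantile normalization, centring on array medians, a variance trend, a robust variance, fits of only the groups compared, the scan strip as a block, other thresholds, other list tests, and leaving out each array. The control and GEMC1 groups had 1 array each on strips 1 and 2, while the MCIDAS arrays were alone on strips 3 and 4. Alternatives added after seeing the data were the mean of the hybridization spikes BioB and BioC as a covariate, the median of olfactory receptor genes as a covariate, and leaving out control replicate 1 and MCIDAS replicate 1 together. Hybridization spikes are bacterial transcripts added to every sample before hybridization. Unchanged groups sharing the 2 controls were simulated 100 times, with errors drawn independently for each gene and array. The simulated arrays thus lack differences between arrays that many genes share. The overlap was taken between called genes, as planned, and between as many top genes by p as had been called, a rule chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.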

Results

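Genome-wide expression was measured in HEK293T cells that received an empty FLAG vector, FLAG-GEMC1 or FLAG-MCIDAS. GEMC1 and MCIDAS are coiled-coil nuclear proteins related to geminin that act early in the differentiation of multiciliated cells. The arrays asked which genes each protein changes in this kidney-derived cell line and, from the title of the series, how this relates to the SWI/SNF chromatin remodelling complexes. There were 2 arrays per group and 6 in all, and 18132 genes were tested. Array pairs correlated between 0.974 and 0.996 (Pearson, across probe sets, which are not independent replicates).

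The transfected genes were looked at first. The only GMNC probe set read 4.93 ± 0.02 (SD, n = 2) log2 units in controls, 4.89 ± 0.05 with GEMC1 and 5.07 ± 0.22 with MCIDAS. Where this probe set lies relative to the plasmid insert was not analysed here, so it does not check the labels. MCIDAS itself was not analysed here. GMNN, which encodes geminin, gave log2 fold changes over control of 0.02 with GEMC1 (adjusted p = 0.949) and -0.13 with MCIDAS (adjusted p = 0.311).

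GEMC1 raised 3 of 19 measured regulators of multiciliated cell differentiation. FOXN4, a forkhead factor of this program, rose by 2.08 ± 0.13 (log2 fold change ± SE, n = 2 arrays per group, adjusted p = 0.013). TP73, a p53 family factor, rose by 1.69 ± 0.09 (adjusted p = 0.00667), and CCNO, a cyclin needed for centriole amplification, by 1.77 ± 0.16 (adjusted p = 0.0332). Among genes past the test, the largest increases were in TCHH (3.00 ± 0.09, adjusted p = 0.00116), which encodes trichohyalin, and in PTN (2.92 ± 0.21), which encodes the growth factor pleiotrophin. EGR1, an immediate early transcription factor, fell by 1.40 (SE 0.09, adjusted p = 0.013).

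Altogether 26 genes rose and 1 fell out of 18132, and 22 of these 27 changed by at least 1 log2 unit. The split was less one-sided without genes below the median of mean value, with 132 higher and 58 lower, and at an unadjusted p under 0.05, with 1049 higher and 1095 lower. Both GEMC1 arrays lay on the same side of both control arrays for each gene just named. ELAVL2, which encodes a neuronal RNA-binding protein, rose by 2.59 ± 0.24, CHRM4, a muscarinic receptor, by 1.98 ± 0.17, and ISM1, a secreted protein, by 1.95 ± 0.09. The control means of ELAVL2 (5.05), ISM1 (5.91) and POU4F2 (5.27) lay under the mean of the background probe sets (6.32), so the size of their changes is uncertain. INSM1 (1.31) and NGFR (1.15) also rose. Named after their values were seen, the transcription factor genes SOX3 (1.67), FOXQ1 (1.54), POU3F1 (1.51), EPAS1 (1.17) and POU4F2 (0.97), as well as GADD45B (1.22), BMP6 (1.20) and NPTX1 (1.01), were also among the 26. The other SOX3 probe set gave -0.078.

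Other regulators of the program did not pass the test at their brightest probe set. CDC20B, whose locus acts in centriole amplification, went from 7.05 ± 0.97 in controls to 10.61 ± 0.16 (SD, n = 2), a log2 fold change of 3.56 ± 0.41 with adjusted p = 0.070. With the median of its 4 probe sets the adjusted p was 0.00749. FOXJ1, the main activator of motile cilium genes, had a log2 fold change of 0.81 ± 0.14 (adjusted p = 0.158) at its brighter probe set and 2.18 at the other, which passed when probe sets were tested one by one (adjusted p = 0.00356). MYB gave 0.53 (adjusted p = 0.390) and RFX3 -0.40 (adjusted p = 0.344). DEUP1 (-0.041, adjusted p = 0.885) and RFX2 (0.062, adjusted p = 0.851) also did not pass, and the 3 RFX2 probe sets ranged from -0.071 to 0.062.

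**Figure D1:**
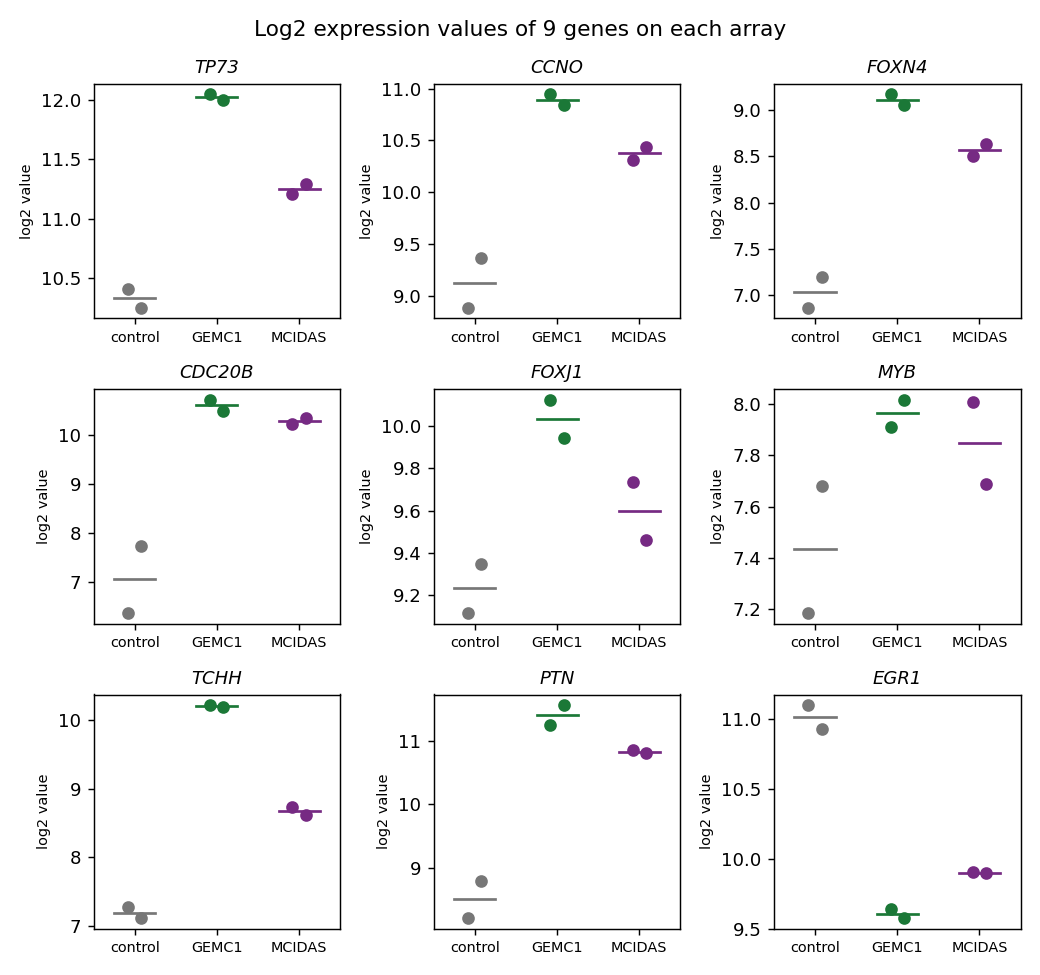
Log2 expression values (vertical axes, log2 units) of 9 genes on each of the 6 arrays, by transfected plasmid (horizontal axes). Points are arrays and lines are group means; the vertical axes do not start at 0. TP73 went from a mean of 10.33 in controls to 12.02 with GEMC1 and 11.25 with MCIDAS, while EGR1 went from 11.01 to 9.61 and 9.90.

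Among the fixed lists, 3 of 19 measured multiciliogenesis regulators rose with GEMC1 (FOXN4, CCNO and TP73) and 16 did not pass, while 4 rose adjusted over the list alone. In the centriole amplification list 1 of 28 members rose (CCNO), or 2 adjusted over the list alone. In the motile cilium axoneme list 1 of 107 rose, CIMAP3 (0.94 ± 0.08, adjusted p = 0.0295), and adjusted over the list alone 3 rose and 1 fell. The median log2 fold change of that list was -0.022, with 47 members above 0 and 60 below. None passed among 21 dynein arm assembly factors (largest DNAAF11, 0.54, adjusted p = 0.350) and 42 genes of intraflagellar transport and the BBSome (IFT74, -0.36, adjusted p = 0.302), with 0 adjusted over each list alone. None of 30 SWI/SNF subunits passed, and 0 did so adjusted over the list alone; the largest value was that of BICRAL (-0.44, adjusted p = 0.335).

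In the neuronal list 2 of 34 genes rose (ELAVL2 and INSM1), and adjusted over the list alone 4 rose and 5 fell. NGFR, listed among airway basal cell markers, was the 1 of 21 members of that list to rise, and also adjusted over the list alone. EGR1 was the 1 of 28 immediate early genes past the test, against 3 higher and 6 lower adjusted over the list alone. In the Notch list 0 of 28 members passed over all genes and 5 rose adjusted over the list alone, with HEY2 at 0.65 (adjusted p = 0.0753). Among 49 DNA replication genes 0 passed over all genes, and 4 rose and 2 fell adjusted over the list alone (RRM2, 0.59, adjusted p = 0.145).

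No member passed in the remaining lists. The members with the largest changes were KIF18A (-0.29) for mitosis, BAX (-0.46) for p53 targets, PPP1R15A (-0.60, adjusted p = 0.0754) for the stress response, HSPA1B (0.44) for heat shock and BST2 (-0.53) for interferon. They were PAX2 (0.56) for kidney epithelium, COL5A1 (-0.42) for fibroblasts, ODF4 (-0.31) for testis, RPL7 (0.21) for ribosomal proteins and COX4I1 (0.26) for the respiratory chain. The 3 COX4I1 probe sets ranged from -0.33 to 0.29. Adjusted over the list alone, 2 p53 targets, 1 stress response gene and 2 fibroblast genes fell, and 0 passed in the other lists of this paragraph.

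Tested as groups with camera, heat shock genes (median 0.12, adjusted p = 0.0061) and respiratory chain genes (0.057, adjusted p = 0.0061) were higher with GEMC1. The p53 targets (-0.13, adjusted p = 0.0061), fibroblast genes (-0.14, adjusted p = 0.0061) and immediate early genes (-0.081, adjusted p = 0.0419) were lower. With an estimated correlation all 5 calls were lost, at an adjusted p = 0.612 for the p53 targets and adjusted p = 0.600 for the other 4. More than the correlation enters this loss. The fibroblast list was estimated at a correlation of -0.01, under the preset 0.01, yet its camera p went from 0.00107 to 0.0357. The lost calls are thus not a measure of correlation alone. The other called lists were estimated above the preset, at 0.263 for p53 targets, 0.136 for the respiratory chain, 0.0931 for immediate early genes and 0.0577 for heat shock. For them a higher correlation enters the loss too. Among random lists matched on mean value the medians stood at percentiles 99.9 for heat shock, 98.3 for the respiratory chain, 0.02 for p53 targets and for fibroblast genes, and 2.42 for immediate early genes. As random lists lack correlation within a list, these ranks are descriptive only. The other 16 lists did not pass, the multiciliogenesis regulators among them (adjusted p = 0.0948, mean 0.33, median 0.022). Median and test differed in sign for the axoneme and DNA replication lists, and for neuronal and interferon genes, and mean and test for airway markers; none of these passed.

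GEMC1 and control arrays shared scan strips 1 and 2. Within strips 1 and 2 the differences were 1.80 and 1.59 for TP73 and 3.10 and 2.91 for TCHH; these genes were picked on the same arrays, so their agreement in sign does not test the strip. With the strip as a fixed block, in a fit of only the control and GEMC1 arrays, limma called 0 genes, against 986 at an unadjusted p under 0.05. A share of 0.05 of unchanged genes passes that threshold by chance. This fit has fewer residual degrees of freedom than the main one, so its count does not show that the strip explains the changes. As a random block it called 10. The count fell to between 1 and 9 without any one of the 6 arrays. It was 1 in a fit of only the GEMC1 and control arrays, and after renewed quantile normalization 28 genes rose and 5 fell.

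MCIDAS also raised FOXN4, CCNO and TP73. CDC20B rose by 3.24 ± 0.41 (log2 fold change ± SE, n = 2 arrays per group, adjusted p = 0.0408), FOXN4 by 1.54 ± 0.13 (adjusted p = 0.0369), CCNO by 1.25 ± 0.16 (adjusted p = 0.0408) and TP73 by 0.92 ± 0.09 (adjusted p = 0.0369). PTN rose by 2.34 ± 0.21, and MORN5, listed among the motile cilium axoneme genes, by 2.62 ± 0.34 (adjusted p = 0.0412). EGR1 fell by 1.11 (SE 0.09), and IGFBP5, an insulin-like growth factor binding protein gene, fell by 1.04 (SE 0.10).

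The test called 621 genes, 453 higher and 168 lower, of which 122 changed by at least 1 log2 unit. Without genes below the median of mean value the direction turned over, with 389 higher and 1178 lower. The largest increases also included the keratin gene KRT32 (2.08), the pseudogene BCRP3 (2.02), the lectin gene CLEC4M (2.02), SERPINA1 (1.97) and the olfactory receptor gene OR4C45 (1.94). Of the 453 genes that rose, 411 (90.7%) had a control mean below the median of all genes. In 103 of them, OR4C45 and GRHL2 included, the control mean lay under the mean of the background probe sets, and in 17 the MCIDAS mean did too. Among 333 olfactory receptor genes, a family chosen after seeing the data and silent in most tissues, the median change was 0.59, 98.2% were above 0 and 11 rose past the test. The hybridization spikes, added to every sample, were 0.47 log2 units higher on the MCIDAS than on the control arrays, against -0.053 for GEMC1. With the spike level as a covariate, an alternative chosen after seeing the data, limma called 0 genes for MCIDAS, against 1517 at an unadjusted p under 0.05. All 621 genes kept their sign, but they were picked on the same arrays. The median change of the 453 higher genes went from 0.75 (median SE 0.11) to 0.60 (0.15), and that of the 168 lower genes from -0.585 (0.088) to -0.51 (0.14).

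Genes that fell with MCIDAS were brighter ones, with a median control value of 9.65 against 7.14 for genes that rose. Besides EGR1 and IGFBP5, the largest decreases were in the sulfotransferase gene GAL3ST4 (-1.01), the thrombin receptor gene F2R (-0.97), the leptin receptor gene LEPR (-0.97), the transcription factor gene TRPS1 (-0.95), TMEM80 (-0.88) and the clathrin adaptor gene AP2A1 (-0.85). Probe sets disagreed in sign for IGFBP5 (-1.04 to 0.033), LEPR (-0.97 to 0.24) and TMEM80 (-0.88 to 0.12), each with the value used at the lower end. Those of GAL3ST4 (-1.01 to -0.177) and AP2A1 (-0.85 to -0.11) agreed in sign, again with the value used at the lower end.

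**Figure D2:**
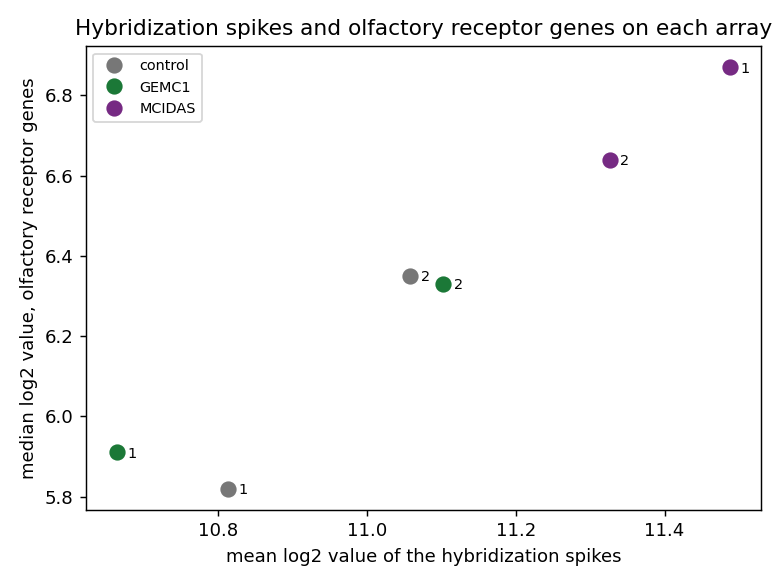
Median log2 value of 333 olfactory receptor genes (vertical axis) against the mean log2 value of the hybridization spikes (horizontal axis) on each array; numbers beside points are replicate numbers and neither axis starts at 0. The MCIDAS arrays lie at 6.87 and 6.64, above the control arrays at 5.82 and 6.35 and the GEMC1 arrays at 5.91 and 6.33.

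In the multiciliogenesis list 4 of 19 members rose with MCIDAS (FOXN4, GRHL2, CCNO and TP73) and 15 did not pass; adjusted over the list alone 4 rose and 3 fell. GRHL2, an epithelial transcription factor, rose by 1.43 ± 0.26 (adjusted p = 0.0499), with its 5 probe sets between 0.0765 and 1.43. FOXJ1 gave 0.37 (adjusted p = 0.127) and 0.89 at its other probe set, MYB 0.42 (adjusted p = 0.174), RFX3 -0.36 (adjusted p = 0.113, with its 3 probe sets from -0.57 to 0.087), RFX2 -0.053 (adjusted p = 0.703) and DEUP1 0.077 (adjusted p = 0.505). Of 28 centriole amplification genes, CDC20B and CCNO rose and POC1B fell by 0.61, while adjusted over the list alone 3 rose and 2 fell. The 3 POC1B probe sets ranged from -0.61 to -0.155, with a median of -0.164.

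Among 107 motile cilium axoneme genes 7 rose, including MORN5, ROPN1L (0.71), ZBBX (0.61) and CCDC40 (0.57), and 0 fell. The 4 CCDC40 probe sets ranged from 0.072 to 0.57. Adjusted over the list alone 29 rose. The list's median was 0.19, and random lists matched on mean value had a median of 0.11. In that ranking it stood at the percentile 98.5. IFT81 rose by 0.59 as the 1 of 42 intraflagellar transport and BBSome genes past the test, also adjusted over the list alone, with its 3 probe sets between -0.075 and 0.59. Of 21 dynein arm assembly factors 0 passed, also adjusted over the list alone (DNAAF6, 0.33, adjusted p = 0.256).

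Genes of DNA replication went both ways, with 3 of 49 higher and 3 lower, and 5 higher and 12 lower adjusted over the list alone. The licensing factor gene CDT1 rose by 0.76, CHAF1B by 0.59 and RRM2 by 0.59, while MCM6, a subunit of the replicative helicase, fell by 0.67. The 3 CDT1 probe sets ranged from 0.061 to 0.76 with a median of 0.114, so the CDT1 call rests on 1 of them. No mitosis gene passed (0 of 52, also adjusted over the list alone; KIF18A, -0.36), and no SWI/SNF subunit passed (0 of 30, also adjusted over the list alone; SMARCD3, -0.47, adjusted p = 0.0716). HES2 rose by 0.41 as the 1 of 28 Notch genes, with 3 higher and 1 lower adjusted over the list alone.

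Some stress genes fell. In the integrated stress and unfolded protein response list 3 of 28 fell, the cystine transporter gene SLC7A11 (-0.62), PPP1R15A (-0.57) and DDIT4 (-0.54), and 9 fell adjusted over the list alone. The p53 targets XPC (-0.52), SPATA18 (-0.49) and the cell death gene BAX (-0.46) were the 3 of 23 that fell, with 5 adjusted over the list alone. EGR1 and JUN (-0.66) fell among 28 immediate early genes, with 10 lower adjusted over the list alone. HSPA1L rose by 0.91 as the 1 of 18 heat shock genes, with 3 higher and 1 lower adjusted over the list alone. IRF9 fell by 0.63 as the 1 of 28 interferon genes, with 3 higher and 5 lower adjusted over the list alone.

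Markers of other cell types were mixed. The basal keratin genes KRT5 (0.83), KRT14 (0.63) and KRT15 (0.62) were the 3 of 21 airway markers past the test, all higher, with 8 adjusted over the list alone. KRT14 and KRT15 both had a control mean of 5.64, under the background mean of 6.32, and MCIDAS means of 6.27 and 6.26, near the background mean of 6.22, so they do not show expression of these keratins. Of 34 neuronal genes 3 rose, ELAVL2 (1.36, from a control mean under background) and PROX1 (1.13) among them, and NCAM1 (-0.75) and SCG2 (-0.73) fell; adjusted over the list alone 4 rose and 3 fell. The 6 NCAM1 probe sets ranged from -0.75 to 0.33, and the 3 PROX1 probe sets from 0.105 to 1.13. Of 25 fibroblast genes PDGFRB rose by 0.40, and SNAI2 (-0.65) and COL6A1 (-0.41) fell, with 2 higher and 8 lower adjusted over the list alone. SPATA3 (0.62) was the 1 of 40 testis genes to rise, also adjusted over the list alone. None of 20 kidney genes passed (CDH6, 0.76, adjusted p = 0.0515), though 7 rose and 3 fell adjusted over the list alone. None of 43 ribosomal protein genes (RPL29, -0.23) and 36 respiratory chain genes (UQCRC1, -0.30) passed, with 0 adjusted over either list alone.

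With camera the axoneme list (adjusted p = 0.000334) and the airway list (median 0.31, adjusted p = 0.000822) were higher with MCIDAS. The stress response list (-0.28, adjusted p = 3.95e-06), p53 targets (-0.19, adjusted p = 0.001), immediate early genes (-0.18, adjusted p = 0.00101), intraflagellar transport (-0.071, adjusted p = 0.0165), DNA replication (-0.086, adjusted p = 0.0203) and fibroblast genes (-0.15, adjusted p = 0.0256) were lower. With an estimated correlation all 8 calls were lost, at an adjusted p = 0.600 for the axoneme, stress response, immediate early and fibroblast lists and adjusted p = 0.647 for the other 4. For the fibroblast list, again estimated at -0.01, the camera p went from 0.00974 to 0.0636, so here too the loss is not a measure of correlation alone. The other called lists were estimated above the preset, from 0.0478 for the axoneme to 0.263 for p53 targets. The airway list was at 0.22 and the stress response list at 0.159, so a higher correlation enters their loss too. Against random lists matched on mean value, intraflagellar transport (percentile 53.7, random median -0.075) and DNA replication (percentile 17.8, random median -0.055) were not set apart. The axoneme and airway lists are dim, with control medians of 7.64 and 7.02, and genes of silent families were higher on the same arrays. With the spike covariate the mean over the axoneme list went from 0.24 (95% interval from its spread between arrays 0.084 to 0.39) to 0.15 (-0.056 to 0.35). That over the airway list went from 0.335 (0.079 to 0.59) to 0.21 (-0.28 to 0.71). The airway list stood at percentile 97.2, with its median of 0.31 below the upper limit of 0.32 of the random range. The stress response list stood at percentile 0, fibroblast genes at 0.17, immediate early genes at 0.35 and p53 targets at 0.51. The random lists lack the correlation estimated within the stress response and p53 lists, so these ranks are descriptive only. The other 13 lists did not pass. The multiciliogenesis list had a median of -0.11 and a mean of 0.19, and its test pointed down. Among the other lists that did not pass, median, mean or test differed in sign for the Notch, interferon, ribosomal and respiratory chain lists.

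The MCIDAS count fell without any single array. Each such fit leaves 1 array in a group and fewer residual degrees of freedom, so the fall does not show that the count rests on particular arrays. Limma called 0 genes without control replicate 1, 1 without control replicate 2, and 0 without either MCIDAS array, against 2956, 6482, 3006 and 5580 genes at an unadjusted p under 0.05. It called 162 without either GEMC1 array. Centring the arrays on their medians gave 613 genes higher and 121 lower. The MCIDAS arrays were alone on scan strips 3 and 4, so no within-strip value exists for them. With strips as a random block 857 genes were called. Only strips 1 and 2 held more than 1 array, and the consensus correlation was -0.297. The block therefore cannot adjust this comparison for the strip, and its count does not test the strip.

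The direct comparison of MCIDAS with GEMC1 asks how the effects of the 2 proteins differ. TCHH was lower with MCIDAS than with GEMC1, by a log2 fold change of -1.52 ± 0.09 (SE, n = 2 arrays per group, adjusted p = 0.0292). Some transcription factor genes that rose with GEMC1 were lower too: POU3F1 (-1.25 ± 0.12), FOXQ1 (-1.04 ± 0.11), INSM1 (-1.01 ± 0.11), EPAS1 (-0.87), POU4F2 (-0.83) and TP73 (-0.77 ± 0.09), all with adjusted p = 0.0454. SOX3 (-0.19, adjusted p = 0.437) and FOXN4 (-0.54, adjusted p = 0.0792) did not pass. EPAS1, POU4F2 and SOX3 are named here after their values were seen. The epidermal keratin gene KRT78 (1.66 ± 0.08, adjusted p = 0.0145) and TMEM130 (1.34 ± 0.09, adjusted p = 0.0292) were higher with MCIDAS.

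In all, 276 genes differed, 207 higher and 69 lower with MCIDAS, 42 of them by at least 1 log2 unit. Without genes below the median of mean value the direction turned over, with 114 higher and 300 lower. Of the 207, 193 (93.2%) had a control mean below the median of all genes, and 7 were olfactory receptor genes. In 48 of them, ZNF732 included, the GEMC1 mean lay under the mean of the background probe sets, and in 6 the MCIDAS mean did too. BCRP3 (1.66), the antisense gene ZNF566-AS1 (1.57), OR10C1 (1.49), LLCFC1 (1.44), ZNF732 (1.38) and STKLD1 (1.37) were among the largest increases. SP8 (-1.06), ISM1 (-1.06), OLFM1 (-0.98) and CRTAC1 (-0.95) were among the largest decreases. Other probe sets of SP8 reached 0.11 and of OLFM1 0.19.

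Of the 26 genes that rose with GEMC1, all 26 had a positive change with MCIDAS and 25 were lower with MCIDAS than with GEMC1, 14 of them past the test and 0 higher past it. These genes were picked for high values on the same GEMC1 arrays, which by itself moves the count this way. Their median log2 fold change over control was 1.38 with GEMC1 and 0.79 with MCIDAS. CCNO (-0.51, adjusted p = 0.115), CDC20B (-0.32, adjusted p = 0.618) and FOXJ1 (-0.44, adjusted p = 0.113) did not differ past the test either, nor did MYB (-0.12), DEUP1 (0.12), RFX2 (-0.12) and RFX3 (0.048). The other probe set gave -1.28 for FOXJ1, -1.09 for MYB and -0.35 for CCNO, and the 4 CDC20B probe sets ranged from -1.06 to -0.32.

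**Figure D3:**
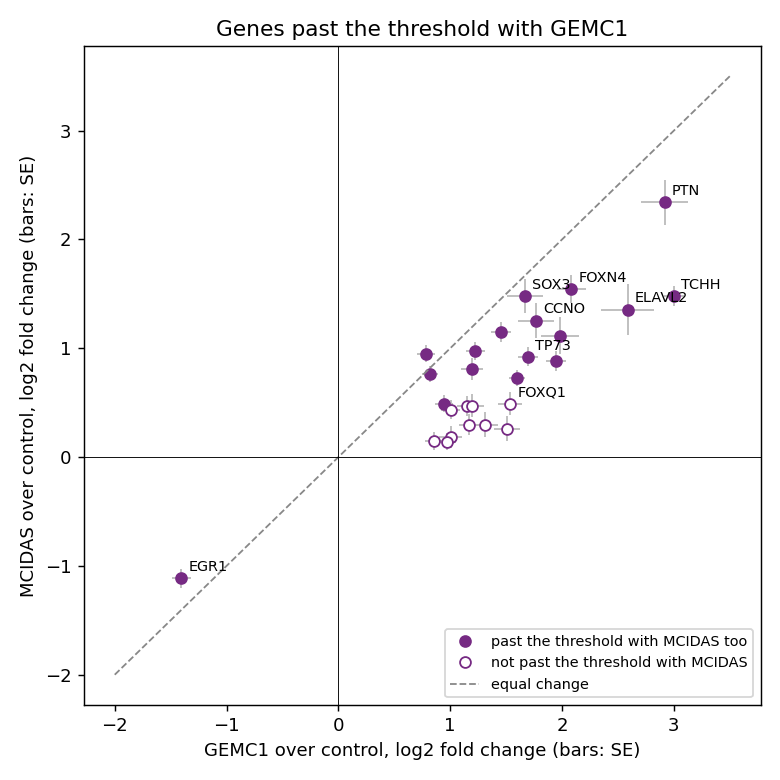
Log2 fold change over control with MCIDAS (vertical axis) against that with GEMC1 (horizontal axis) for the 27 genes past the threshold with GEMC1; bars are SE and the dashed line marks equal change. Of the 26 genes that rose with GEMC1, 25 lie below the line, and 17 of the 27 genes also passed the threshold with MCIDAS.

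In the direct comparison 1 of 19 multiciliogenesis regulators was lower (TP73), with 1 higher and 2 lower adjusted over the list alone. None of 28 centriole genes passed, also adjusted over the list alone. The axoneme genes EFHB (0.61), CCDC40 (0.60) and ODAD1 (0.54) were the 3 of 107 higher with MCIDAS, with 19 higher and 2 lower adjusted over the list alone. DNAAF19 (0.47) and IFT81 (0.64) were each the 1 gene past the test in the dynein assembly list of 21 and the transport list of 42, also adjusted over the lists alone. The IFT81 probe sets ranged from -0.17 to 0.64, and their median per array gave -0.047. The Notch targets HES1 (-0.65) and HEY2 (-0.53) were lower, 2 of 28, with 2 higher and 2 lower adjusted over the list alone.

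DDIT4 (-0.60) was the 1 of 28 stress response genes that was lower, with 4 adjusted over the list alone, and DUSP4 (-0.83) the 1 of 28 immediate early genes, with 2 higher and 2 lower adjusted over the list alone. HSPA1L (0.91) was the 1 of 18 heat shock genes that was higher, also adjusted over the list alone. INSM1 was lower and TUBB3 (0.52) higher among 34 neuronal genes, with 2 higher and 2 lower adjusted over the list alone. KRT5 (0.90) was higher and NGFR (-0.68) lower among 21 airway markers, with 11 higher and 1 lower adjusted over the list alone. PDGFRB (0.54) was higher and SNAI2 (-0.79) lower among 25 fibroblast genes, with 2 higher and 1 lower adjusted over the list alone. SPATA3 (0.74) was the 1 of 40 testis genes higher, also adjusted over the list alone.

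No member passed in the lists for DNA replication (CCND1, -0.52, adjusted p = 0.0569), mitosis (SPC25, -0.36), SWI/SNF (BCL11A, -0.41, adjusted p = 0.0775), p53 targets (XPC, -0.39), interferon (RSAD2, 0.82, adjusted p = 0.154), kidney (CDH16, 0.68, adjusted p = 0.0613), ribosomal proteins (RPL7, -0.27) and the respiratory chain (SDHD, -0.38). Adjusted over the list alone, 3 kidney genes were higher and 2 lower, and 0 passed in the others. The 8 BCL11A probe sets ranged from -0.91 to 0.13. With camera the axoneme (0.17, adjusted p = 0.00025) and airway lists (0.35, adjusted p = 0.000617) were higher with MCIDAS. The stress response (-0.18, adjusted p = 0.000104), transport (-0.12, adjusted p = 0.00119), DNA replication (-0.11, adjusted p = 0.00229), respiratory chain (-0.087, adjusted p = 0.00249) and multiciliogenesis lists (-0.15, adjusted p = 0.0132) were lower. With an estimated correlation all 7 calls were lost, each at an adjusted p = 0.506. As in the comparisons with control, this loss is not a measure of correlation alone. All 7 lists were estimated above the preset, from 0.0478 for the axoneme to 0.22 for the airway list. Against random lists matched on mean value, the axoneme list (percentile 85, random median 0.13) and the transport list (percentile 8.95, random median -0.072) were not set apart. With the spike covariate the mean over the axoneme list went from 0.225 to 0.122 (95% interval -0.094 to 0.34) and that over the airway list from 0.31 to 0.18 (-0.35 to 0.71). The airway list stood at percentile 98.6, the multiciliogenesis list at 2.31, DNA replication at 2.17, the respiratory chain at 0.33 and the stress response at 0.01. Here too the ranks are descriptive only. The other 14 lists did not pass. Among those, median, mean or test differed in sign for heat shock, interferon and fibroblast genes.

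For MCIDAS over GEMC1 limma called 0 genes without any one of the 6 arrays, with the spike level as a covariate and in a fit of only these 2 groups. At an unadjusted p under 0.05 there were between 2449 and 5464 genes without 1 array, 1323 with the covariate and 5464 in the fit of 2 groups.

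The comparisons with control shared genes. Of the 27 genes called with GEMC1, 17 were called in the same direction with MCIDAS, 16 higher and 1 lower, and 0 in opposite directions. The 17, listed in full whether or not the naming rule takes them, were AMPH, BMP6, CCNO, CHRM4, CIMAP3, ELAVL2, FOXN4, GADD45B, IGFBPL1, ISM1, PAQR4, PTN, SOX3, TCHH, TMEM132E and TP73, which rose, and EGR1, which fell. The SOX3 probe sets ranged from -0.11 to 1.48 with MCIDAS. Independent lists of these sizes would share 0.65 higher genes and 0.00927 lower genes. Both comparisons use the same 2 controls, which by itself gives overlap. In 100 simulations of unchanged groups sharing them, the called genes, the measure planned beforehand, overlapped by 0.04 genes on average and at most 2. Only 0.15 genes were called there for GEMC1 and 0.31 for MCIDAS on average, so that measure cannot show what shared controls give to longer lists. The 27 and 621 simulated genes with the lowest p shared 15.1 genes in the same direction on average, between 10 and 23. The overlap of 17 lies in that range. These simulated genes enter by rank without passing the test, so the ranked comparison cannot decide either.

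Across genes, which are not independent replicates, the fold changes correlated at a Pearson r of 0.43, against a mean of 0.498 in the simulations. Their covariance was 0.0296, against 0.00911 simulated, a difference of 0.0205, while 62.5% of genes had the same sign, against 66.7% simulated. The simulated arrays lack differences between arrays that many genes share, such as those between the 2 controls. The excess covariance therefore does not show a shared effect of the 2 proteins. The overlap was between 0 and 2 genes without any one array, and the covariance was between 0.00662 without GEMC1 replicate 2, under the simulated value, and 0.0824 without control replicate 2.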

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

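All tests on the patterns below were chosen after the results were seen, except the first held-out test, which was written down before its result was known. Signals outside the genes tested were looked for first. Among the 4305 probe sets with no gene symbol or several, 13 passed the threshold with GEMC1 over control, all higher, and 261 with MCIDAS over control, 167 higher and 94 lower. The hybridization spikes, which the gene tests do not use, were 0.472 log2 units higher on the MCIDAS than on the control arrays, with all 5 spike probe sets between 0.449 and 0.497.

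The olfactory receptor genes were higher on the MCIDAS arrays (median 0.59). An effect of MCIDAS alone is argued against by the controls, which never received it. Control replicate 2 lay 0.423 above control replicate 1 in the median of the differences per gene, with 91.6% of 333 genes higher. The background probe sets did not rise, with a median change of -0.0884 and 0 of 23 higher. Their values were taken after RMA, which adjusts for background, so they cannot exclude a raised background on all probes. An array gradient shared by all groups remains a candidate explanation. The array with the higher spike level was the higher one in both pairs, by a median difference per gene of 0.395 within GEMC1 and 0.423 within controls. With the spike covariate the MCIDAS median was -0.0155, and what sets the gradient, such as the amount of RNA or the labelling, was not tested.

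The genes raised by GEMC1 were raised less by MCIDAS. With the spike covariate the median MCIDAS over GEMC1 change went from -0.717 (median SE 0.0935) to -0.665 (0.171), with 25 of 26 below 0, while the calls ended as the SE grew. The covariate is fitted on differences between arrays of a group, and these genes were called in part because such differences were small. It could therefore hardly move them, and an array gradient is not excluded. The mean over these genes with the covariate was -0.694 (95% interval from its spread between arrays -1.02 to -0.367), an interval that does not allow for picking the genes on the same arrays. Picking genes on the GEMC1 arrays may also create the pattern. The test written beforehand picked 26 genes on 1 GEMC1 and 1 control array of a strip and compared the held-out GEMC1 array with the MCIDAS mean; it gave a median of 0.868 with 100% above 0 one way and -1.18 with 30.8% above 0 the other, which by its own rule came out for selection. That second pick set an array of higher spike level against a lower one, and the first did the reverse, so all 4 pairings were run afterwards. They gave -1.18, 0.41, 0.671 and 0.868. The pick behind -1.18 held only 7 of the 26 genes that rose with GEMC1, against 14 to 17 in the other pairings, so it bears mainly on other genes. With both signs among the pairings selection stays open, and the amounts of the 2 proteins were not measured.

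The stress response list was lower with MCIDAS. Control arrays standing apart are argued against, as the whole cause, by the comparison with GEMC1, which leaves them out: the median was -0.183, with 24 of 28 members below 0, and the mean over the list was -0.217 (95% interval from its spread between arrays -0.368 to -0.0666). A gradient stays open. With the spike covariate the MCIDAS over control median went from -0.28 to -0.161, with 24 of 28 below 0, and the mean from -0.277 (-0.428 to -0.127) to -0.195 (-0.44 to 0.0492). Over GEMC1 the covariate took the median to -0.102 and the mean to -0.126 (-0.388 to 0.136), so a gradient and apart controls together stay open too. The list test did not pass with an estimated correlation, and an effect of MCIDAS stays open as a hypothesis.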

How the results depend on the processing

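The covariates and the joint removal of control replicate 1 and MCIDAS replicate 1 were chosen after seeing the data. In every setting with 1 value per gene, all 27 genes called for GEMC1 that were tested kept their sign. All 621 for MCIDAS and all 276 for MCIDAS over GEMC1 did so too, except with the median (608 and 270) or mean (619 and 275) of a gene's probe sets. The genes were picked on the same arrays, so this agreement in sign is no independent test. The counts moved much more, and the cause was not tested unless fewer arrays or genes enter by construction.

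For GEMC1 over control, with 27 genes called as reported, the count was 50 with the median and 62 with the mean of a gene's probe sets, 61 with probe sets one by one, 47 and 190 without genes below the lower quartile or the median of mean value, 96 with a variance trend, 63 at an adjusted p under 0.1, 79 with the spike covariate and 114 with the olfactory receptor covariate, both of which kept all 27. It was 1 in a fit of only the groups compared, 10 with the strip as a random block (consensus correlation -0.297), and 0 in limma with the strip as a fixed block (986 at an unadjusted p under 0.05) or without the 2 end arrays (981). Without single arrays it was 1 to 9, a lone array being assumed to vary like the other groups.

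For MCIDAS over control, with 621 as reported, it was 1348, 1566 and 2391 with the median, mean and single probe sets, 1200 and 1567 under the filters, 2152 with a variance trend, 3989 at an adjusted p under 0.1, 122 at a log2 change of at least 1 and 162 in a fit of only these groups. Above the median of mean value 24.8% of calls were higher, against 72.9% as reported. Limma called 0 with the spike covariate (1517 at an unadjusted p under 0.05), the olfactory receptor covariate (1583) or without the 2 end arrays (1462), and 0 to 162 without single arrays. The spike level is higher on both MCIDAS arrays, so the covariate also takes up part of the group difference.

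For MCIDAS over GEMC1, with 276 as reported, it was 695 with the mean of probe sets, 166 after renewed quantile normalization, 180 after centring, 2413 at an adjusted p under 0.1 and 42 at a log2 change of at least 1. Limma called 0 in a fit of only these groups (5464), with the spike (1323) or olfactory receptor covariate (1809), without the 2 end arrays (2481) and, as both the lowest and the highest value, 0 without single arrays. IFT81 reversed to -0.047 with the median of its probe sets.

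Lists called were 0 for all 3 comparisons with fry and with an estimated correlation, a loss that, as described above, is not a measure of correlation alone. For GEMC1 (5 as reported) they were 8 without the 2 end arrays and 1 to 8 without single arrays. For MCIDAS (8) they were 5 above the median of mean value. For MCIDAS over GEMC1 (7) they were 4 above the lower quartile, 1 above the median and 4 with the spike covariate. Genes called the same way by both (17) were 26 with the median of probe sets, 27 and 114 under the filters, 9 with the random block, 0 with the spike covariate, 0 without the end arrays and 0 to 2 without single arrays. The covariance was 0.0162 without the end arrays and 0.00662 to 0.0824 without single arrays. With 2 arrays per group, signal near background limits what can be said of dim genes.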

Other observations

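Families of genes outside the fixed lists were looked at after seeing the data. Of 82 keratin-associated protein genes, which encode hair shaft proteins, 10 rose with MCIDAS over control and 0 fell, with a median log2 fold change of 0.33 and 93.9% above 0. The control median of this family, 6.35, lay near the background mean of 6.32. With the spike covariate 0 genes of any kind were called for MCIDAS over control. With GEMC1 the median log2 fold change of the keratin-associated genes was -0.046, and 0 passed. Of 23 bitter taste receptor genes 0 passed with MCIDAS, at a median of 0.29. Within the control pair the keratin-associated median was 6.23 on replicate 1 and 6.43 on replicate 2. The median of the differences per gene was 0.072, with 67.1% of genes higher on replicate 2.

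The first principal component held 69.4% of the variance over the 6 arrays. Its scores were -30.4 and -4.52 for the control arrays, -22.4 and -1.15 for the GEMC1 arrays and 38.1 and 20.4 for the MCIDAS arrays. The spike levels were 10.81 and 11.06 for control, 10.66 and 11.10 for GEMC1 and 11.49 and 11.33 for MCIDAS. Within each pair the array with the higher spike level had the higher score. The component thus also follows the array gradient and cannot be read as an effect of MCIDAS alone. On the second component, with 14.3% of the variance, the scores were 14.9 and 8.34 for control, -14.3 and -12.9 for GEMC1 and 4.37 and -0.477 for MCIDAS.

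At its other probe set MYB, a regulator of early multiciliated cell differentiation, had a log2 fold change of 1.31 with GEMC1 and 0.22 with MCIDAS, against 0.53 and 0.42 at the probe set used. All 9 TP73 probe sets were higher in both comparisons, between 1.14 and 1.84 with GEMC1 and between 0.60 and 1.07 with MCIDAS.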
